A study of Mus musculus with 3 samples.

How the data were processed

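MicroRNAs (miRNAs) were measured on 2-colour Exiqon miRCURY LNA arrays in 3 mouse samples, with 1 array per sample and 1 sample per group. Per the labels, total RNA was purified with Trizol, each sample was labelled with the dye Hy3, and a pool made from equal amounts of the 3 samples was labelled with Hy5 and used as the common reference on every array. The deposited scanner tables give, for each spot and dye, the signal mean, signal median, background median and background standard deviation as an intensity on a linear scale, not yet normalized, per the file headers. They also give a quality flag, which is a score set by the authors' image analysis, per the file headers. The scanner, the image analysis software and its version are not given in the sources used here. A further deposited table holds the authors' processed values, which look like log2 values of sample over pool: its medians were 0.12 for control, -0.05 for non-malignant ICN1 and -0.17 for ICN1 tumor. Its exact normalization and centring stay unknown, and its row numbers could not be matched to probes (1 of 345 occurred in the scanner tables). It was therefore used only to count differences between its columns. No column of values was left unassigned to a sample.

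Every array had 6720 spots for 1491 probe identifiers, most with 4 replicate spots. Flags were the same for both dyes. Spots with flag 3 were left out (72 on the control, 125 on the non-malignant ICN1 and 51 on the ICN1 tumor array), and spots with flags 2 and 4 were kept, since they were taken to mark empty or negative spots. No spot outside the control spots was saturated in either dye. Background was corrected with the normexp method (offset 50) on signal mean and background median, and log2(Hy3/Hy5) was normalized within each array by global loess with the control and mismatch spots at weight 0 (limma 3.58.1, R 4.3.3). Ratios were averaged over the replicate spots of a probe. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

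The design assumed mouse miRNA names on the array. The probes carry human names instead, so a human-named probe was used where a mouse miRNA gene of that name is listed in the RefSeq annotation of GRCm38.p6, which served for names and for finding genes that start within 10000 bases of each other, and no coordinate is given. In this way 276 probes were matched. Left outside the comparisons were 175 human-named probes without a mouse gene of that name and 736 probes without a known human target. The 151 probes named miRPlus and 118 mismatch probes also stayed outside. The match used names only, and whether a probe's sequence equals that of the mouse miRNA was not checked. No probe has the name miR-709, which the list of miRNAs reported by the study also holds, so miR-709 is not analysed here. A probe counted as detected on an array where at least 1 of every 2 usable spots had a Hy3 signal mean above the background median plus 2 background standard deviations. A probe entered a comparison if it was detected on at least 1 of its 2 arrays. Where it was detected on 1 of them only, the difference is given as "at least N-fold". That bound sets the brighter array's normalized Hy3 value, after loess and A-quantile scaling, against the higher of the dim probe's own value and the lowest value among detected probes on the dim array. It is open to dye bias because no dye swap was made, and it holds only for the reported normalization, since other scalings gave smaller differences for the same probes. Where the fold of the ratio itself is smaller than this bound, as for miR-31 in tumor against control, that fold is given instead. The ratio alone is given for miR-150, and for miR-146b in tumor against control.

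With 1 array per group no test between groups was possible and no p-value is given. A difference is the log2 ratio of one array minus that of another. Its standard error comes from the replicate spots and covers the error of the spots, not of the animals or cultures. The size rule was a difference of 2-fold or more. The pool's Hy5 signal, which should be equal on all arrays, gave a technical comparison. For each miRNA list, the median difference of the detected members was placed as a percentile among 10000 random lists of the same size, drawn from the detected mouse miRNA probes in 5 bins of mean intensity. A list was called apart from the random lists below percentile 2.5 or above percentile 97.5. The lists were the miR-17-92 and paralog clusters, the let-7 family, the miR-181 family, a textbook list of MYC-repressed miRNAs, the miR-23/27/24 clusters, the miR-34 family, activation and inflammation miRNAs, the Dlk1-Dio3 imprinted cluster, the Sfmbt2 intron cluster, and tRNA-derived sequences. Further lists were markers of erythroid, myeloid, mature lymphocyte, stromal, epithelial, and muscle or liver cells, the pan-haematopoietic miR-142 arms, and miRNAs reported by the study. The groups, lists, tests and the settings listed first below were fixed before the data were examined. Named miRNAs were, per comparison, up to 10 with the largest differences in each direction that passed the size rule and whose replicate spots did not overlap between arrays, together with miR-451 and up to 4 members of each list, plus members needed to state a count.

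The alternatives were a normexp offset of 10, no background correction, spot medians, median centring, print-tip loess, no normalization, the Hy3 channel alone after quantile normalization, no filter on dim probes, detection on all 3 arrays, all spots kept, the median of replicate spots, loess fitted on mouse miRNA probes only, a 3-fold size rule, unmatched random lists and the authors' value table. Centring on the spike-in controls and detection on both arrays of a comparison were chosen after seeing the data.

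The procedure was tested on simulated data built from the pool-channel levels of the control array, for the tumor against control comparison, with 200 of 482 detected probes changed. All 50 probes made 6-fold higher and 47 of 50 made 3-fold higher passed the size rule. Among probes made lower, 34 of 50 passed at 6-fold and 34 of 50 at 3-fold. The median difference at 6-fold lower was -1.66 on the log2 scale, because dim probes reach the background, so the size of a lower value is understated for dim probes. None of the 282 unchanged probes passed. The simulated noise held errors of spots but no error of a whole probe on an array, so this does not measure false calls on the real arrays. On those, the pool signal was 2-fold or more off the median at 6 of 177 mouse miRNA probes in tumor against control. Of 200 random lists of 10 unchanged probes, 10 fell outside the percentile limits.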

Results

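The series profiled miRNAs in CD4+CD8+ (double-positive) T cells of mice on a Balb/c background, in a study of T-cell acute lymphoblastic leukaemia. ICN1 is the intracellular, constitutively active part of the receptor NOTCH1. The 3 samples were normal control thymocytes, non-malignant cells that express ICN1, and ICN1 tumor cells, with 1 array each, so every difference below has no replicate check and the number of arrays limits the precision. The labels give no age or time point for the samples, so any such difference between them goes with the groups. Of the 276 probes that name a miRNA with a mouse gene, 60.1% were detected in control cells, 56.2% in non-malignant ICN1 cells and 60.9% in ICN1 tumor cells, and 179 were detected on at least 1 array. The median Hy3 background was 77, 82 and 70 intensity units on these arrays. Detection may not have been specific to mouse miRNAs, but the other probes cannot settle it. There were 175 human-named probes without a mouse gene of that name. Of these, 88 passed on the control array, 83 on the non-malignant array and 93 on the tumor array. The match was by name only, so some of these may target a mouse miRNA listed under another name. Of the 736 probes without a known human target, 456, 412 and 488 passed on these arrays. That name does not tell whether they target a mouse miRNA, so mouse miRNAs may be among them and outside the comparisons. Differences are in log2 units of the ratio of sample to pool, and ± is the standard error of the difference over up to 4 replicate spots per array. Probes of one miRNA family are not independent. Probes with 1 mismatch kept a median of 0.198 of the perfect-match signal over 54 pairs on the control array, so related miRNAs may share signal.

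The first comparison asked how miRNAs differed in cells that express ICN1 but are not malignant. In these cells, miR-500 was 4.0-fold higher than in control cells (2.0 ± 0.023). The related miR-449 and miR-449b, which share their seed sequence with the miR-34 family, were higher by 1.53 ± 0.017 and 1.44 ± 0.035. The myeloid miRNA miR-223 was higher by 1.19 ± 0.021, and miR-21, which is induced in many tumors, by 1.13 ± 0.017. miR-9 was higher by 1.08 ± 0.034, and its opposite strand miR-9*, not detected in control cells, was at least 2.16-fold higher as scaled here and differed by 1.03 with the Hy3 channel alone. On the lower side, miR-26a differed by -1.31 ± 0.0089, the erythroid miRNA miR-451 by -1.19 ± 0.0085 and miR-23a by -1.13 ± 0.018.

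These 7 higher and 3 lower probes were all that reached 2-fold among 167 detected mouse miRNA probes, and the other 157 lay between. The pool signal differed between the same arrays with an SD of 0.16, and 95% of probes lay within 0.26 of the median. With the Hy3 channel alone the split was 5 higher and 1 lower, and with loess fitted on mouse miRNA probes it was 7 higher and 1 lower. The difference of miR-451 was then -0.34 and -0.76, under 2-fold in both, as was miR-23a (-0.98 and -0.89). With Hy3 alone miR-223 (0.93) and miR-9 (0.70) were under 2-fold too, and miR-9 was so in 4 further settings.

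Among the lists, the miR-181 family, which tunes T-cell receptor signalling in thymocytes, had a median of -0.46 over 4 detected probes, at percentile 1.0 of matched random lists, or -0.29 with all spots kept. Its members were miR-181a* (-0.63), miR-181a (-0.61), miR-181b (-0.30) and miR-181c (0.0026), none of them at 2-fold. The miR-23/27/24 clusters had a median of -0.40 over 6 probes (percentile 1.1), with 1 probe at 2-fold lower, miR-23a, beside miR-27a (-0.75), miR-24 (-0.62) and miR-189 (-0.18). The MYC-repressed list had a median of -0.24 over 18 probes (percentile 2.2), which was -0.15 with median centring and -0.12 with loess on mouse miRNA probes, with miR-26a the 1 probe at 2-fold lower, then miR-26b (-0.63), miR-146a (0.47) and miR-16 (-0.45). Activation miRNAs lay at the other end, with a median of 0.12 over 7 probes (percentile 98.3), which was 0.073 without normalization, 0.21 with median centring and 0.22 with detection on all 3 arrays. Of these miR-21 was at 2-fold higher, and miR-146a, which restrains NF-kappaB signalling, differed by 0.47, miR-155 by -0.40 and miR-222 by 0.22.

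All 10 let-7 family probes lay below 0, with none at 2-fold and a median of -0.36 (percentile 6.9), from let-7a and let-7a-e (both -0.51) and let-7d (-0.48) to miR-98 (-0.18), though let-7b and let-7c lay at 0.089 and 0.12 and the median at -0.13 with loess on mouse miRNA probes. All 12 probes of the miR-17-92 and paralog clusters also lay below 0, with a median of -0.28 (percentile 7.2) and values of -0.59 and -0.57 for 2 miR-20a probes and -0.54 for the shared miR-17-5p and miR-106a probe. With loess on mouse miRNA probes this median was -0.041, and miR-106b, miR-18a, miR-18b and miR-25 lay just above 0. The erythroid markers differed in direction: miR-451 was lower, miR-486 differed by -0.31 and miR-144, whose gene neighbours that of miR-451, by 0.72 (median -0.31, percentile 20.7, or -0.19 with loess on mouse miRNA probes). The miR-142 arms, abundant in all blood cells, differed by -0.44 (-5p) and -0.14 (-3p), a median of -0.29 (percentile 41.1) that was 0.15 with Hy3 alone and 0.10 with loess on mouse miRNA probes. Medians of the remaining lists were 0.033 for 14 Dlk1-Dio3 probes (percentile 90.4), -0.096 for 2 miR-34 family probes (percentile 22.3) and 0.0045 for 4 stromal probes (percentile 63.0). They were 0.0083 for 3 epithelial probes (percentile 58.9) and 0.0012 for 4 muscle and liver probes (percentile 63.4), and the Dlk1-Dio3, stromal, epithelial and muscle and liver signs turned without normalization. The lymphocyte miRNA miR-150 differed by -0.13, and by 0.081 with median centring and 0.028 with loess on mouse miRNA probes.

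**Figure D1:**
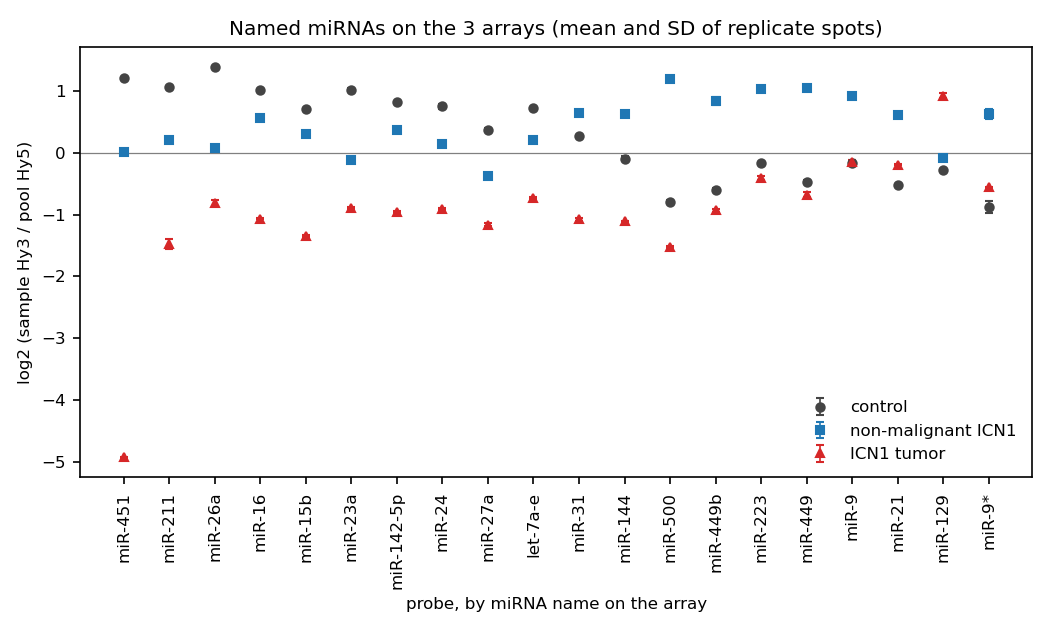
Log2 ratio of sample (Hy3) to pool (Hy5) for the miRNAs with the largest differences, on the control, non-malignant ICN1 and ICN1 tumor arrays (1 array each); points are means and bars are SDs of the replicate spots. miR-451 lies at 1.21 in control cells, 0.017 in non-malignant ICN1 cells and -4.93 in ICN1 tumor cells.

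The second comparison set ICN1 tumor cells against control cells. In tumor cells miR-451 was 70.2-fold lower (-6.13 ± 0.0074), with a mean Hy3 signal of 575 against 23705 in control cells. miR-211 was lower by 5.81-fold (-2.54 ± 0.039), or by -1.57 with Hy3 alone, and the pool signal at its spots was 0.82 higher on the tumor array after centring. The neighbouring pair miR-16 and miR-15b, known repressors of BCL2, differed by -2.08 ± 0.0069 and -2.06 ± 0.0075, or by -1.21 and -1.20 with loess on mouse miRNA probes. miR-26a, which represses EZH2, differed by -2.21 ± 0.022. The 3 neighbours miR-23a, miR-24 and miR-27a were also lower, miR-23a by -1.90 ± 0.018, miR-24 by -1.66 ± 0.025 and miR-27a, not detected in tumor cells, at least 2.21-fold as scaled here (-1.13 with median centring). The pan-haematopoietic miR-142-5p differed by -1.78 ± 0.010 and the let-7a-e probe by -1.45 ± 0.010. A single mouse miRNA probe was at 2-fold higher, miR-129 (1.21 ± 0.023, under 2-fold at 0.95 without normalization).

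Of 177 detected mouse miRNA probes, 26 were at least 2-fold lower and 1 at least 2-fold higher. The pool signal varied more here than in the first comparison, with an SD of 0.34 and 95% of probes within 0.80 of the median. The 10 spike-in controls differed by a median of 0.10. With loess fitted on mouse miRNA probes only, which moved the median of all these probes by 0.16, 9 probes were lower and 6 higher. miR-451 differed by -4.91 in that setting and by -3.99 with the Hy3 channel alone. Of the 27 probes at 2-fold, 10 stayed so in that loess setting, where let-7a-e was at -0.30, miR-142-5p at -0.74 and miR-106b at -0.23, and 17 stayed so with Hy3 alone.

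The list with the most lower probes was the MYC-repressed one. All 19 of its detected probes lay below 0, 8 of them at 2-fold lower, with a median of -0.97 that lay at percentile 0 of matched random lists and was -0.53 with loess on mouse miRNA probes. The 8 were miR-26a, miR-16, miR-15b, miR-26b (-1.45), miR-30b (-1.32), miR-22 (-1.16), miR-29a (-1.13) and miR-30c (-1.06). With loess on mouse miRNA probes only the first 3 stayed at 2-fold, with miR-26b at -0.98, miR-30b at -0.86, miR-22 at -0.83, miR-29a at -0.67 and miR-30c at -0.53, and with Hy3 alone miR-30b (-0.97), miR-29a (-0.84) and miR-30c (-0.89) were under 2-fold. Of the 19, miR-34a and miR-29c lay above 0 in at least 1 other scaling. In the miR-23/27/24 clusters 4 of 6 probes were at 2-fold lower, the 3 named above and miR-23b (-1.26, under 2-fold at -0.76 with loess on mouse miRNA probes), with a median of -1.40 (percentile 0), or -1.20 with probes undetected on 1 array at their bound. Both miR-142 arms were at 2-fold lower, with a median of -1.53 (percentile 12.6, -0.95 with Hy3 alone and -0.25 with loess on mouse miRNA probes), but miR-142-3p, at -1.29 ± 0.0072, was at 0.23 in that setting and -0.21 with Hy3 alone. All 10 let-7 probes lay below 0 and 3 were at 2-fold lower, let-7a (-1.45), let-7a-e and let-7d (-1.11), with a median of -0.91 (percentile 13.0). In that loess setting the median was -0.29, none of the 3 stayed at 2-fold (let-7d, at -0.57, did not with Hy3 alone either), and let-7b, let-7c and miR-98 lay at 0.10, 0.28 and 0.070.

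In the miR-181 family 1 of 5 probes was at 2-fold lower, miR-181a (-1.24 ± 0.025), beside miR-181a* (-0.93), miR-181b (-0.64) and miR-181c (0.15), with a median of -0.64 (percentile 12.9). That median was -0.080 with Hy3 alone and -0.24 with loess on mouse miRNA probes, and miR-181a was at -0.89 in both. The miR-17-92 and paralog clusters, which promote lymphoid growth, had 1 of 12 probes at 2-fold lower, miR-106b (-1.18), with miR-19a at -0.69, miR-19b at -0.51 and a miR-20a probe at -0.45. Their median of -0.25 lay at percentile 49.5, and was 0.12 with loess on mouse miRNA probes, -0.00031 with the Hy3 channel alone and -0.44 without normalization. Of the erythroid markers, miR-451 and miR-144 (-1.02 ± 0.020) were at 2-fold lower and miR-486 was at -0.76, with a median of -1.02 (percentile 10.2). miR-144 was under 2-fold with Hy3 alone (-0.57), with loess on mouse miRNA probes (-0.69), without background correction and with print-tip loess (both -0.95), and the pool signal at its spots was 0.63 higher on the tumor array after centring. The list of miRNAs reported by the study holds only miR-451 here and is no independent evidence of its direction.

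Lists of the remaining cell types had no probe at 2-fold. The myeloid miR-223 differed by -0.24 (0.17 with loess on mouse miRNA probes and -0.48 with Hy3 alone), and no other myeloid marker was detected. The stromal median was 0.013 over 4 probes (percentile 78.9, of the other sign in 5 other scalings) and the muscle and liver median -0.016 over 4 probes (percentile 57.3, above 0 with median centring and with loess on mouse miRNA probes). The epithelial median of 0.21 over 3 probes was called apart from matched random lists (percentile 98.8), with miR-200b and miR-203 both at 0.21 and miR-200c at -0.063, and was 0.37 with loess on mouse miRNA probes, 0.34 with a normexp offset of 10, 0.11 with spike-in centring and without normalization, and 0.0053 with no filter on dim probes. The activation list had a median of -0.18 over 6 probes (percentile 45.4), from miR-146b (-0.71) and miR-155 (-0.67) to miR-222 (0.38). Of these miR-146b was not detected in tumor cells, and its -0.71 is the ratio alone. The list median ran from -0.28 with spike-in centring to 0.033 with loess on mouse miRNA probes and 0.13 with probes detected on all 3 arrays. The Dlk1-Dio3 cluster had a median of 0.018 over 15 probes (percentile 96.5, negative without normalization, with print-tip loess and with spike-in centring), with miR-654 at 2-fold lower (-1.30 ± 0.087, but -0.96 with Hy3 alone and -0.86 with loess on mouse miRNA probes, both under 2-fold). The miR-34 family median was -0.18 over 2 probes (percentile 46.0), and 0.0084 with loess on mouse miRNA probes. miR-150, not detected in tumor cells, differed by -0.20, and by -0.55 with a normexp offset of 10 to -0.031 with median centring. Further probes at 2-fold lower were miR-31, not detected in tumor cells and at least 2.54-fold lower as scaled here (-1.04 with median centring), miR-128a (-1.09) and miR-128b (-1.01), of which both miR-128 probes were under 2-fold with Hy3 alone (-0.85 and -0.97) and with loess on mouse miRNA probes (-0.62 and -0.57), and miR-128b also without background correction and with print-tip loess (both -0.94).

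**Figure D2:**
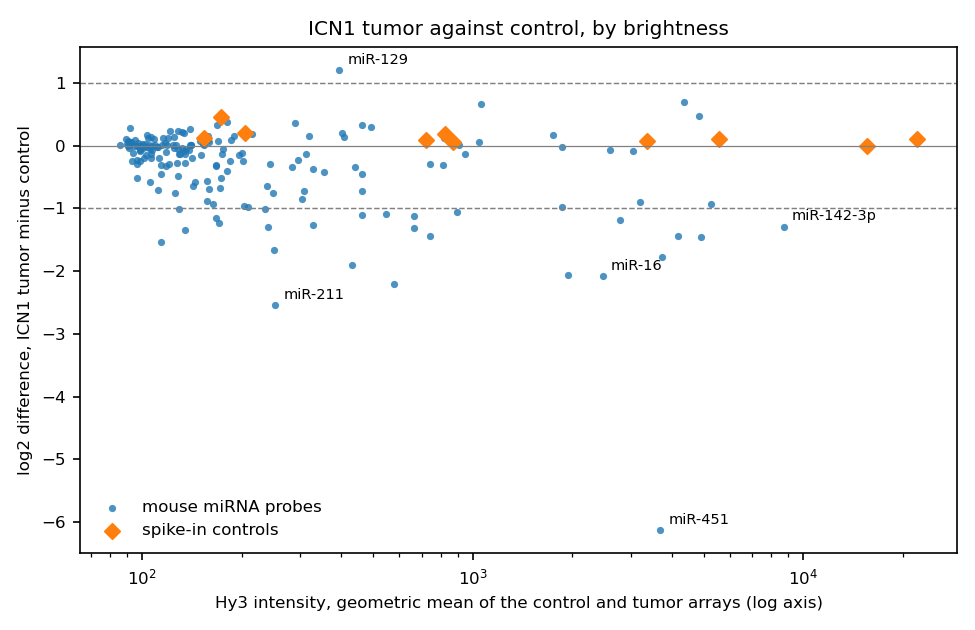
Log2 difference of the ratio, ICN1 tumor minus control, against the geometric mean of the Hy3 intensities of both arrays (log axis), for 177 mouse miRNA probes (circles) and 10 spike-in controls (diamonds); dashed lines mark 2-fold. The spike-in controls lie between -0.00018 and 0.45 at all intensities, and 26 miRNA probes lie at or below the lower line.

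The third comparison set ICN1 tumor cells against non-malignant ICN1 cells, both of which express ICN1. miR-451 was 30.8-fold lower in tumor cells (-4.94 ± 0.0067) and its neighbour miR-144 differed by -1.74 ± 0.0068. Probes that were higher in non-malignant than in control cells lay below 0 here, and because the same non-malignant array serves both comparisons these values are not independent. miR-500 differed by -2.73 ± 0.019 (-3.55 with Hy3 alone), miR-449b by -1.76 ± 0.035, miR-449 by -1.73 ± 0.020 and miR-223 by -1.43 ± 0.027. The pool signal at the miR-500 spots differed by -1.18 between the tumor and control arrays after centring. miR-9*, not detected in tumor cells, was at least 2.06-fold lower as scaled here and miR-9 differed by -1.07, while miR-21 differed by -0.80. Both miR-9 strands lost 2-fold in other settings, miR-9* with Hy3 alone (-0.95), with median centring (-0.98) and without normalization (-0.94), and miR-9 in 6 settings, among them Hy3 alone (-0.56) and loess on mouse miRNA probes (-0.90). miR-31, not detected in tumor cells, was at least 3.22-fold lower as scaled here (-1.38 without normalization), miR-211 differed by -1.68 ± 0.040 (-1.02 with Hy3 alone), miR-15b by -1.65 ± 0.014 and miR-16 by -1.64 ± 0.0059.

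In all, 17 of 174 detected probes were at least 2-fold lower in tumor cells and 1 was higher, miR-129 (1.0 ± 0.021), which fell short of 2-fold under 7 of the other settings. With loess on mouse miRNA probes 12 were lower and 3 higher. The pool signal differed between these arrays with an SD of 0.39, and 95% of probes lay within 0.82 of the median. miR-451 differed by -3.65 with the Hy3 channel alone.

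The erythroid markers had a median of -1.74 over 3 probes (percentile 0.30), with miR-451 and miR-144 at 2-fold lower and miR-486 at -0.45. With Hy3 alone the median, which is that of miR-144, was -0.98, under 2-fold. All 19 MYC-repressed probes lay below 0, with a median of -0.70 (percentile 0.10, -0.39 with loess on mouse miRNA probes) and 3 at 2-fold lower, miR-15b, miR-16 and miR-22 (-1.31), then miR-146a (-0.96), while miR-29b, miR-29c and miR-34a lay above 0 in at least 1 other scaling. The miR-23/27/24 clusters had a median of -0.78 over 6 probes (percentile 0.40), or -0.66 with bounds, with miR-23b (-1.08) and miR-24 (-1.05) at 2-fold lower, though both were under 2-fold (-0.83 and -0.76) with loess on mouse miRNA probes, as was miR-24 (-0.87) with Hy3 alone. Both miR-142 arms were at 2-fold lower, miR-142-5p at -1.33 and miR-142-3p at -1.15, with a median of -1.24 (percentile 13.5). With loess on mouse miRNA probes both were under 2-fold, at -0.66 and -0.036, with a median of -0.35, and miR-142-3p was also under 2-fold with Hy3 alone (-0.42) and print-tip loess (-0.98). The miR-17-92 and paralog clusters lay above most matched random lists (percentile 98.5) with no probe at 2-fold. Their median of 0.044 was below 0 with median centring, without normalization and with spike-in centring, and 0.24 with loess on mouse miRNA probes. Their members ran from miR-106b (-0.86) and miR-19a (-0.37) to a miR-20a probe (0.31) and miR-20b (0.57).

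The let-7 family had a median of -0.60 over 10 probes, all below 0 and none at 2-fold (percentile 19.5), led by let-7a and let-7a-e (both -0.94), though let-7b, let-7c and miR-98 lay at 0.012, 0.17 and 0.079 with loess on mouse miRNA probes and the median at -0.12, or at -0.38 with Hy3 alone. The activation list had a median of -0.54 over 6 probes (percentile 5.4, and from -0.33 to -0.27 in 5 other settings), with miR-146b, not detected in tumor cells, at least 1.61-fold lower as scaled here (-0.58 without normalization). The miR-181 family had a median of -0.32 over 4 probes (percentile 33.6), with miR-181a at -0.62, and of -0.038 with Hy3 alone and -0.050 with loess on mouse miRNA probes. Medians lay near 0 for 15 Dlk1-Dio3 probes (-0.0059, percentile 94.0), 2 miR-34 probes (-0.087, percentile 35.7), 4 stromal probes (0.0085, percentile 78.6), 3 epithelial probes (-0.066, percentile 44.4) and 3 muscle and liver probes (-0.041, percentile 50.9), and each of these took the other sign under at least 1 scaling. miR-150 differed by -0.078, with overlapping spots. No probe matched the Sfmbt2 intron cluster or the tRNA-derived sequences.

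**Figure D3:**
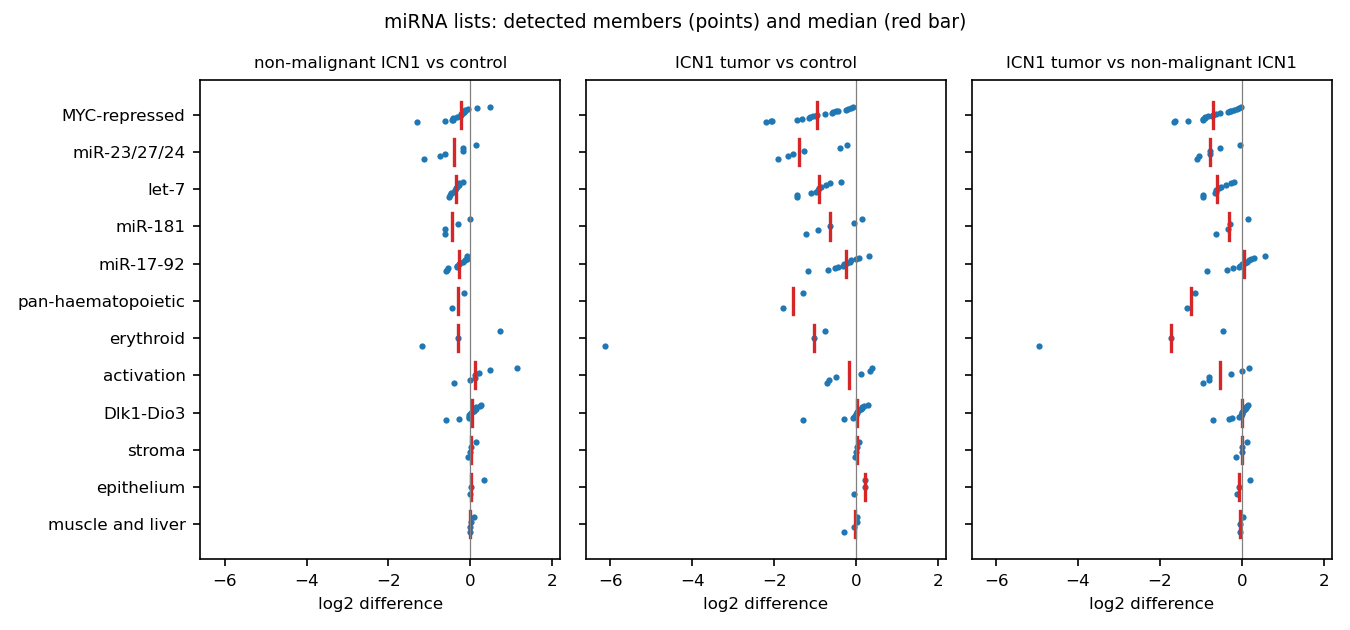
Log2 differences of the detected members (points) and their median (red bar) for 12 miRNA lists in the 3 comparisons, with 1 array per group. In tumor against control the MYC-repressed median lies at -0.97 and the miR-23/27/24 median at -1.40, and the stromal and the muscle and liver medians lie at 0.013 and -0.016, with the sign of these last medians dependent on the scaling.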

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

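All explanations weighed here were tested only after the pattern had been seen, and there is 1 array per group.

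miR-451 was lower in ICN1 tumor cells than in control cells by -6.13 on the log2 scale. A pool channel of another brightness at these spots covers little of it: the median-centred Hy5 signal was higher by 1.023 on the tumor array. Less erythroid RNA in the tumor sample stays open, with miR-144 and miR-486, the other erythroid markers, at a median of -0.8884 and miR-144 close to background in control cells (Hy3 signal of 165). The miR-486 probe was brighter (359) and differed by only -0.76, which counts against erythroid RNA as the whole explanation, but it is 1 probe and its level in T cells is unknown. A biological difference between tumor and control cells also stays open, as untested.

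More miRNA probes were lower than higher on the tumor array, 26 against 1. Normalization of the array as the whole explanation is argued against by the spike-in controls, whose median difference was 0.1014 where the lower probes had a median of -1.33. The split still depended on the scaling, at 9 lower and 6 higher with loess on mouse miRNA probes. The mean Hy3 signal was 367 on the tumor and 599 on the control array, and the mean Hy5 signal 490 and 597. The spike-in controls do not measure the quality of the sample RNA, which stays open. A brighter pool channel is argued against for the 26 lower probes as a set, since their median Hy5 difference was -0.2697 after centring. Single probes ran from -0.58 to 1.02, and the pool was brighter at miR-451 (1.02), miR-211 (0.82) and miR-144 (0.63). Less small RNA per total RNA in the tumor sample may contribute and cannot be told apart from miRNA-specific change: the U6 and snoRNA probes had a median of -0.1973 but went both ways, from -0.66 to 0.60. A biological difference between tumor and control cells also stays open, as untested.

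A signal outside the main measurement appeared in 7 probes that carry no miRNA name. They were at least 2-fold higher on the tumor array than on the control array, and the non-malignant array had 0 such probes. On the tumor array 12 probes of the same kind (11 without a known human target and 1 miRPlus) were at least 2-fold lower. The 7 were a small share of the detected probes of this kind. Between the same arrays the pool signal was 2-fold or more off the median at a larger share of all detected probes. The 7 are therefore not shown to lie beyond the technical spread. With miR-129, miR-637 and miR-659 the 7 make 10 higher probes, with a median ratio difference of 1.20. The pool signal at these probes was dimmer in 8 of 10, with a median of -0.4573 after centring, which may account for part of the difference. With the Hy3 channel alone, which leaves the pool out, the 10 probes had a median of 1.325 (from 0.86 to 1.83). For the 10 as a set this cannot tell whether a dimmer pool is the whole of the difference. The probes were picked for a high ratio on these same arrays, and the Hy3 values were quantile-scaled. Unscaled Hy3 signals were higher on the tumor array at miR-637, miR-659 and some of the probes without a miRNA name. At others they were lower or nearly unchanged. What else lies behind the difference was not tested.

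The probe with 1 mismatch to miR-144 was brighter than the perfect-match probe on every array and differed by 1.551 between non-malignant ICN1 and control cells, with Hy3 signals of 930 and 374. It differed by -1.22 in tumor against control and by -2.77 in tumor against non-malignant cells. On the control array 7 of 54 probes with 1 mismatch were brighter than their perfect match.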

How the results depend on the processing

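Spike-in centring and detection on both arrays were chosen after seeing the data. Of 96 counts of probes at 2-fold under other settings, 72 were within 1.5 times the reported count. With loess on mouse miRNA probes, tumor against control had 9 lower and 6 higher, tumor against non-malignant cells 3 higher, and non-malignant against control cells 1 lower. That setting moved the spike-in median from 0.10 to 0.74 in tumor against control. In simulated data with the 60 brightest miRNA probes made 3-fold lower, it gave a median of -0.12 for them, against -1.38 in the reported setting. A fit on bright probes that all fall together must follow them, so this does not tell which setting is right for the real arrays. With as many simulated probes made higher as lower, loess on mouse miRNA probes gave -1.67 for those 6-fold lower, against -1.66. With the Hy3 channel alone, non-malignant against control cells had 1 lower, tumor against control 2 higher and tumor against non-malignant cells 0 higher. Under the 3-fold rule, the counts of higher and lower probes were 1 and 0 in non-malignant against control, 0 and 8 in tumor against control, and 0 and 9 in tumor against non-malignant cells, as a stricter rule must give fewer. The authors' value table had 4 higher and 3 lower of 104 rows in non-malignant against control. It had 5 higher and 23 lower of 98 rows in tumor against control, and 0 higher and 13 lower of 92 rows in tumor against non-malignant cells. The probe class of these rows is unknown, so the counts are not over the same probes as the reported ones. The single higher probe in tumor against control was lost without normalization (0). The single higher probe in tumor against non-malignant cells, miR-129 at 1.0, was lost (0) without background correction, with spot medians, median centring, print-tip loess, no normalization and spike-in centring, and the count was 2 with a normexp offset of 10. In tumor against control, miR-142-3p reversed to 0.23 with loess on mouse miRNA probes. In tumor against non-malignant cells, the miR-17-92 list median reversed to -0.088 with median centring, -0.053 without normalization and -0.020 with spike-in centring. The cause was not tested. miR-451 stayed at 2-fold lower in both comparisons with tumor cells in every setting that gave it a value, from -6.26 to -3.99 against control. No row of the authors' table could be matched to miR-451. The lowest differences of any row in that table were -6.11 in tumor against control and -4.93 in tumor against non-malignant cells. Of the 27 probes at 2-fold in tumor against control, 17 stayed so with Hy3 alone and 10 with loess on mouse miRNA probes. With unmatched random lists 5 of 39 percentiles crossed a limit, among them let-7 in all 3 comparisons (0.60, 0.40 and 1.1). No leave-one-out was possible with 1 array per group, and no paired analysis was possible because each group has 1 sample. Signal over background limits the dim probes, whose differences are understated.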

Other observations

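The neighbouring genes of several named miRNAs gave a further description, chosen after the values were seen, with genes counted as neighbours when they start within 10000 bases of each other. miR-15b and miR-16 differed by -2.06 and -2.08 in tumor against control cells, but by -1.54 and -2.01 with the Hy3 channel alone, while miR-15a, which neighbours the other miR-16 gene, differed by -0.97 ± 0.013 (-0.42 with Hy3 alone). In the cluster of miR-23a, miR-27a and miR-24 all 3 probes lay below 0 in both comparisons with control cells. In the paralogous cluster miR-27b differed by 0.14 ± 0.019 (0.025 with Hy3 alone) in non-malignant ICN1 cells, where miR-23b differed by -0.18 ± 0.012 (0.063 with loess on mouse miRNA probes). Tumor against control cells gave values below 0 for both, -0.40 for miR-27b and -1.26 for miR-23b (-0.76 with loess on mouse miRNA probes). miR-451 and miR-144 differed in opposite directions in non-malignant cells, by -1.19 and 0.72. miR-500 was higher by 2.0 in non-malignant cells, and the probes for its neighbours miR-501 and miR-362 were not detected on any array.

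Among probes without a miRNA name, some of the brightest were lower in tumor cells. A miRPlus probe with a Hy3 signal of 32314 in control cells differed by -2.65 between tumor and control cells, and a probe without a known human target, at 51327 in control cells, differed by -1.99. The bright human-named probe miR-659 was higher by 1.17, with unscaled signals of 4733 in control and 6403 in tumor cells. The pool signal at its spots differed by -0.45 on the tumor array after centring, so part of the 1.17 may come from the pool.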
